A study of Bos taurus with 9 samples.

How the data were processed

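The series holds 9 RNA sequencing libraries of bovine blastocysts at day 8, 3 for each of 3 oocyte maturation media: control with 5.5 mM glucose, low glucose with 2.75 mM, and low glucose with 1.8 mM BHB. Each library came from a pool of 9 to 11 embryos. Per the labels' protocols, polyadenylated RNA was enriched and libraries were made with a NEBNext Ultra II kit. The deposited table holds estimated counts per gene, which need not be whole: 23.4% of the values are not whole numbers. Per the submitters' processing notes, fastp, kallisto and DESeq2 were used and the genome build was bosTau9. Versions, the annotation and the role of each tool are not given in the sources used here. Kallisto assigns reads that match several transcripts by estimation, so near-identical copies share reads. Groups were taken from the sample titles, and columns were matched to samples by the descriptions in the labels.

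The table lists 22127 genes, 21643 of them protein coding, 466 pseudogenes and 18 others. Symbols came from the table for 17706 genes and, for 323 more, from a RefSeq gene table of another assembly, ARS-UCD2.0, used for names alone. 4098 genes stayed without a symbol. No coordinates are given. Total estimated counts per library ran from 55611205 to 75178898. The exact counting intervals and the floors cover counting error only, while intervals of fold changes from the fit also cover the spread between libraries. No pair of replicates agreed within sampling noise: log2 CPM correlated at 0.951 to 0.976 within groups, and the smallest chi-square per degree of freedom was 45.1.

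Estimated counts were rounded to whole numbers and fitted in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total 15), which left 16469 genes and put 5658 aside. Libraries were scaled by TMM factors. A single quasi-likelihood fit of all 9 libraries with 3 group means gave each comparison, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.322. Standard errors were derived from the fold change and the F statistic, and intervals are at 95%. Values in CPM are means of TMM-scaled CPM with the SD over libraries, and principal components used log2 CPM with a prior count of 2.

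Before the data were examined, 37 gene lists were fixed, covering metabolism, stress, chromatin, signalling, embryo lineages and other cell types. Of these, 34 had at least 5 tested members and were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and adjustment over the lists. Of the lists that passed, 2 against control in low glucose, 2 against control with BHB and 0 between the low glucose media held with an estimated correlation. The design, the alternatives and the rule for named genes were also fixed before the data were examined. The rule took per comparison the 10 largest rises and falls without overlap among genes with a symbol past the threshold, the 5 genes of smallest p in a direction with fewer than 5 passing genes, the 4 leading members of each list that passed, up to 3 passing members of each other list, and 14 genes of interest whatever their values. Genes named outside it are marked as chosen after their values were seen, except the interferon tau genes, of which all tested members are named. For named genes with 1 to 3 counts in a group, ratios of scaled counts with exact counting intervals are given, and for groups with no counts a bound against 3 counts over the group.

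The steps were tested on simulated data with known changes. In 3 simulations per comparison with 100 genes changed at each fold, edgeR recovered 41.0%, 43.7% and 46.3% of 2-fold and 73.3%, 67.0% and 71.0% of 4-fold changes for low glucose against control, BHB against control and BHB against low glucose, with 6.15%, 6.18% and 7.20% of calls false. Simulated groups without differences gave the correlation and covariance of fold changes between comparisons that share controls. The replicate numbers were checked for pairing by correlating deviations from the group means. Between the low glucose media every pair was over 0.1 (0.115, 0.243 and 0.102), so the numbers pair these samples by that rule, from the data and not from the labels.

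Alternatives were RLE factors, no filter and a mean count of at least 50, the replicate number as a block, fits of only the 6 libraries compared, DESeq2 1.42.0, limma-voom, camera with an estimated correlation, fry, and leaving out each library in turn. Added after the data were seen were thinning to the smallest library and a comparison of both low glucose media together against control, with the bounds for both set before they were run. A list of sex markers had 0 of 14 genes in the table, and the lists of interferon tau and genome activation genes had 3 and 4 tested members, too few for the list test. Figures were drawn with matplotlib 3.10.9.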

Results

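RNA sequencing measured transcripts in 9 libraries, each from a pool of 9 to 11 bovine blastocysts collected at day 8. The oocytes, still within their cumulus cells, had been matured for a day in 1 of 3 media, with 3 libraries per medium. Control medium held 5.5 mM glucose, low glucose medium held 2.75 mM, and the last held 2.75 mM glucose with 1.8 mM BHB, taken here as the ketone body beta-hydroxybutyrate, which the labels do not spell out. Fertilisation and embryo culture were the same for all groups. Total estimated counts per library ran from 55611205 to 75178898. The series asks whether the maturation medium of the oocyte leaves a mark on the transcripts of the blastocyst. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

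Control blastocysts stood apart from those of both low glucose media in the most variable genes, but not in correlations over all tested genes. Over all tested genes, log2 CPM correlated at 0.932 to 0.978 between groups, against 0.951 to 0.976 within them. Control replicates 2 and 3 correlated more with low glucose with BHB replicate 3 (0.973 and 0.971) than with control replicate 1 (0.953 and 0.951). On the first principal component, which held 31.0% of the variance of the 500 most variable genes, the control libraries lay at -40.3, -22.6 and -21.9 and the other 6 between 2.08 and 29.4. On the next component, with 18.3% of the variance, replicate 1 of each medium lay above the others of its medium, at 33.8 for control, 10.8 for low glucose and 20.8 for low glucose with BHB. Mitochondrially encoded transcripts took 5.01% ± 0.316 of counts in control, 5.98% ± 1.79 in low glucose and 3.93% ± 2.03 with BHB (SD, n = 3 each). Low glucose replicate 1 held the most, 7.93%, and replicate 2 with BHB the least, 2.25%.

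**Figure D1:**
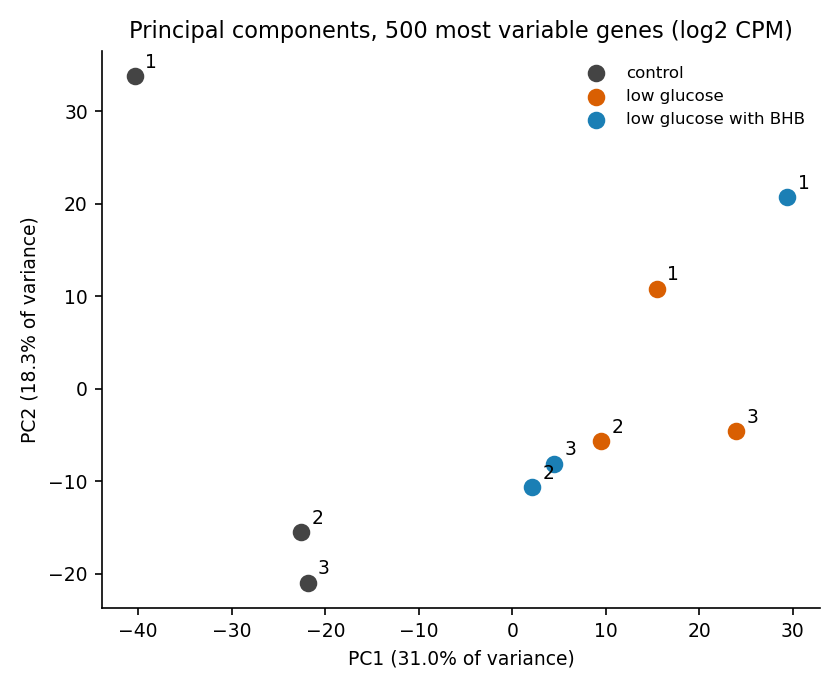
Principal components of log2 CPM over the 500 most variable tested genes, with PC1 on the x axis and PC2 on the y axis. Each point is a library, coloured by medium and marked with its replicate number. The 3 control libraries lie below 0 on PC1 and the other 6 above 0.

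Blastocysts from low glucose medium held less of many transcripts than controls, among them genes of the interferon response and of the extracellular matrix. MX1, an antiviral GTPase induced by interferon, fell from 98.2 ± 18.0 CPM in control to 8.39 ± 2.48 CPM (SD, n = 3 each). LUM, which encodes the matrix proteoglycan lumican, fell from 139 ± 59.2 to 14.3 ± 9.21 CPM, and COL5A1, a fibrillar collagen gene, from 76.7 ± 8.33 to 9.82 ± 6.18 CPM. Transcription factors of the pluripotent and trophoblast lineages, among them POU5F1, NANOG and CDX2, did not pass the test. In edgeR's quasi-likelihood test, 333 of 16469 genes were lower and 1, C1R, was higher at an adjusted p under 0.05. The falls had a median log2 fold change of -2.15, or 4.43-fold, and 279 of them belong to none of the fixed gene lists.

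Of 34 measured genes of the interferon response, 23 fell in low glucose, or 28 adjusted over the list alone, with a median log2 fold change of -2.48. The list passed camera's test with the preset correlation (adjusted p = 8.26e-75) and with an estimated correlation (adjusted p = 0.0143). With the member that had no counts in low glucose set at its bound, the median was also -2.48. MX1 had a log2 fold change of -3.55 (SE 0.334, edgeR adjusted p = 0.000712) and IFIT5, an RNA-binding antiviral effector, -3.55 (SE 0.395, edgeR adjusted p = 0.00105). USP18, which removes ISG15 from proteins, changed by -2.32 (SE 0.243), and DDX58, which encodes the RNA sensor RIG-I, by -2.32 (SE 0.246). RTP4 changed by -4.67 (SE 0.706) and IFI44 by -4.18 (SE 0.661). Neither STAT2 nor IRF7, genes chosen after their values were seen, passed, at -0.04 (SE 0.125) and -0.01 (SE 0.142). Markers of cumulus and granulosa cells were lower in the same libraries, with a list median of -1.05. Members such as MX1, IFIT5 and IFI44 belong to gene families, and reads shared between similar copies make single members uncertain.

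**Figure D2:**
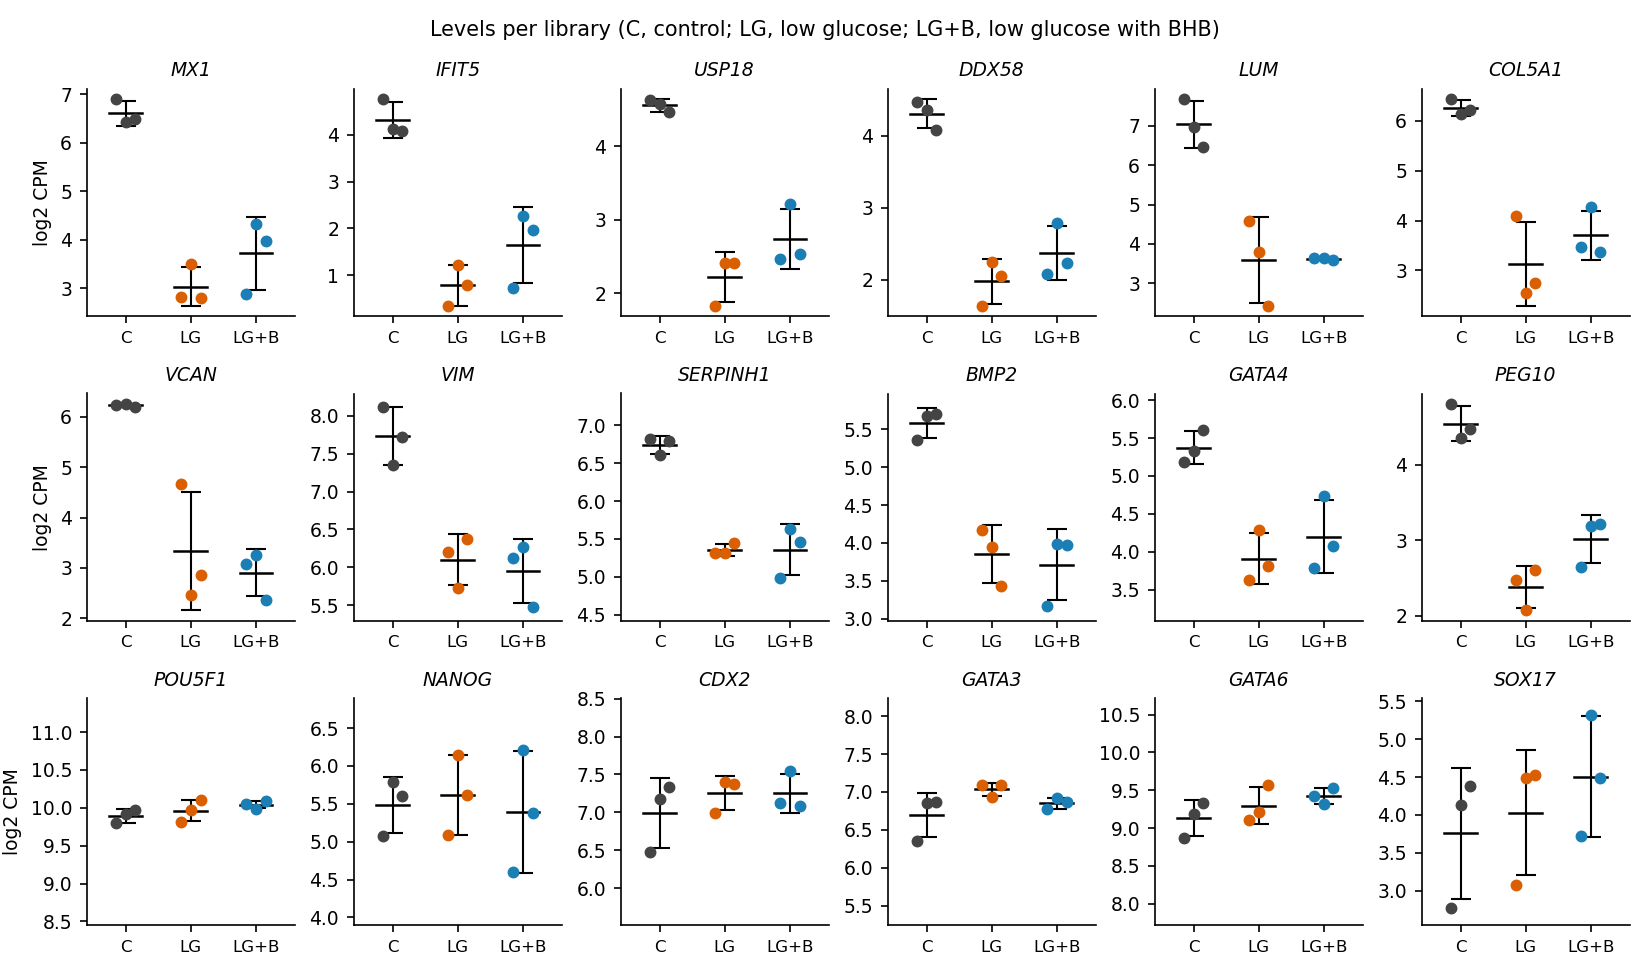
Log2 CPM per library (y axes) of 18 genes in control (C), low glucose (LG) and low glucose with BHB (LG+B), with axes that do not start at 0. Points are libraries, and bars are the mean and SD of 3 libraries. The control libraries of MX1 to PEG10 lie above all libraries of the other media, while those of NANOG, CDX2, GATA6 and SOX17 overlap with them.

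Matrix and adhesion genes fell as well, 8 of 38 measured, or 16 adjusted over the list alone, with a median log2 fold change of -0.63. That list passed camera with the preset correlation (adjusted p = 4.96e-16) but not with an estimated correlation (adjusted p = 0.0759), and its median was -0.36 without control replicate 1. COL5A1 changed by -2.97 (SE 0.377, edgeR adjusted p = 0.00177), the integrin gene ITGAV by -1.87 (SE 0.226), the hyaluronan receptor gene CD44 by -2.22 (SE 0.326) and VIM, an intermediate filament gene, by -1.64 (SE 0.241). FN1, chosen after its values were seen, did not pass, at 4933 ± 325 CPM in control and 6316 ± 280 CPM in low glucose. The fixed list of cumulus and granulosa cell markers fell by 1.05 in median, with 6 of 23 genes lower, or 10 adjusted over the list alone. Its call held with an estimated correlation (camera adjusted p = 0.0335). LUM changed by -3.28 (SE 0.442, edgeR adjusted p = 0.00222), DCN, another small proteoglycan gene, by -2.14 (SE 0.360), and NR5A2, an orphan nuclear receptor gene, by -1.71 (SE 0.246). Other markers of these cells, chosen after their values were seen, did not pass: CYP19A1 (aromatase) stood at -0.12 (SE 0.216) and FSHR at 0.21 (SE 0.250).

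Of 27 hypoblast markers, 4 fell, or 6 adjusted over the list alone, with a median of -0.17, and the call was lost with an estimated correlation (camera adjusted p = 0.256). Their median turned to 0.02 without control replicate 1, and was -0.31 without control replicate 2, -0.09 without control replicate 3 and -0.04 without low glucose replicate 2. The members that fell were SERPINH1, a collagen chaperone, at -1.39 (SE 0.157), BMP2 at -1.71 (SE 0.241), the connexin gene GJA1 at -2.25 (SE 0.367) and the transcription factor gene GATA4 at -1.45 (SE 0.246). GATA6 and SOX17, further hypoblast transcription factors, did not pass, at 0.17 (SE 0.148) and 0.25 (SE 0.473). Imprinted genes had 3 falls among 24, or 4 adjusted over the list alone, and a median of -0.13 (camera adjusted p = 0.0797 with an estimated correlation). PEG10, a paternally expressed gene of the placenta, fell from 23.6 ± 3.96 to 5.25 ± 0.973 CPM, and MAOA from 4.39 ± 0.781 to 0.906 ± 0.177 CPM. The list of WNT, TGF-beta, FGF and Hippo signalling had 2 falls among 38, ID3 and FGFR1, or 5 adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.0812 with an estimated correlation), or -0.22 without low glucose replicate 1. FGFR1 lost its call without control replicate 1 (-0.95) or 3 (-0.83) and without low glucose replicate 1 (-0.85) or 2 (-0.91). POU5F1 was measured at 954 ± 60.5 CPM in control and 1002 ± 99.2 CPM in low glucose, a log2 difference of 0.07 (SE 0.106), and CDX2 at 0.23 (SE 0.210). Epiblast and pluripotency markers had no member past the threshold and a median of 0.12 (camera adjusted p = 0.106). Of the interferon tau genes of the trophoblast, 3 were tested and none passed, with a median of -0.00439, and of the genome activation genes 4 were tested and none passed, with a median of 0.08.

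Further genes fell outside the lists that passed. HIF1A, the oxygen-sensitive transcription factor gene, fell from 93.0 ± 14.5 to 41.9 ± 4.64 CPM. IGFBP7, an insulin-like growth factor binding protein gene, fell from 170 ± 38.1 to 41.4 ± 1.81 CPM, and FOXO1, a transcription factor gene restrained by insulin signalling, from 14.7 ± 6.42 to 2.00 ± 0.507 CPM. GSTA1, a glutathione transferase gene, changed by -3.65 (SE 0.412, edgeR adjusted p = 0.00110). The acute-phase gene ORM1 had 456 counts over the control libraries and 1 over those of low glucose, a ratio of 449 (exact 95% counting interval 80.2 to 17773), but control replicate 1 held 326 of these counts, and without it the ratio was 183. PI15 had 361 counts and 3, a ratio of 118 (40.2 to 577). Genes of glucose and ketone use did not pass. SLC2A1, a glucose transporter gene, stood at 0.12 (SE 0.106), the monocarboxylate transporter gene SLC16A1 at 0.28 (SE 0.169), and the ketone enzyme genes BDH1 and OXCT1 at -0.04 (SE 0.278) and -0.40 (SE 0.198). TXNIP, which is induced by glucose, stood at -1.31 (SE 0.313, edgeR adjusted p = 0.0575). DNMT1, DNMT3A and HDAC1 stood at -0.05 (SE 0.151), 0.19 (SE 0.168) and 0.11 (SE 0.130). The glycolysis list had no member past the threshold, or 1 lower adjusted over the list alone. It had a median of 0.00157, a mean of -0.12 and a downward test (camera adjusted p = 0.606). Ketone body genes had 0 past the threshold, or 1 lower adjusted over the list alone, a median of 0.04, a mean of -0.09 and a downward test (camera adjusted p = 0.836).

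Small upward shifts were shared by lists of translation and mitochondrial genes in which no single gene passed, 0 also adjusted over the list alone. Ribosomal protein genes had a median log2 fold change of 0.18 over 76 genes, nuclear genes of oxidative phosphorylation 0.10 over 72, unfolded protein response genes 0.20 over 21, mitochondrially encoded transcripts 0.31 over 13 and trophectoderm markers 0.12 over 32. All 5 passed camera only with the preset correlation. With an estimated correlation the adjusted p was 0.794 for each of them except the trophectoderm list, where the adjusted p was 0.718. The trophectoderm gene CLDN7 stood at 213 ± 34.2 CPM against 159 ± 14.8 CPM in control, and GATA3 at 131 ± 7.77 against 105 ± 19.9 CPM. Without control replicate 1 the calls for oxidative phosphorylation (0.03) and trophectoderm (0.09) were lost. Without low glucose replicate 1, the library richest in mitochondrial transcripts, those for mitochondrial transcripts (0.04), unfolded protein response (0.12) and trophectoderm (0.14) were lost, and without control replicate 3 that for mitochondrial transcripts (0.30). The median of mitochondrial transcripts was 0.54 without low glucose replicate 3, and that of trophectoderm markers 0.21 without control replicate 3.

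At 1207 genes, the count at an unadjusted p under 0.05 exceeded the 823 that chance gives, and C1R kept its call only without control replicate 2 in 9 fits that each left out a library, and the other 8 gave 0.95 to 1.42. Leaving out control replicate 3 left 196 genes and leaving out low glucose replicate 2 left 197, while DESeq2 gave 583.

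**Figure D3:**
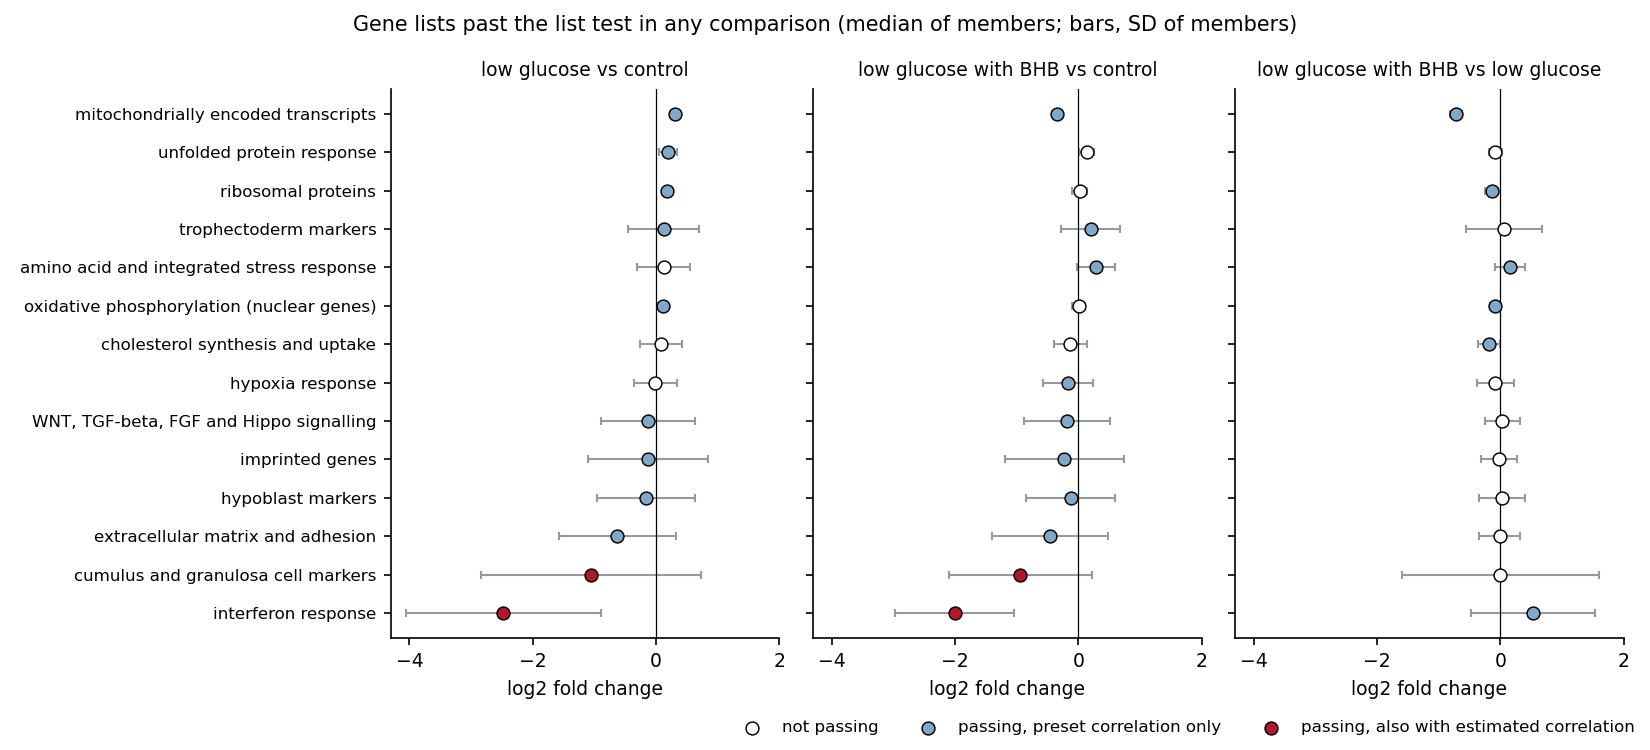
Median log2 fold change of the members (x axes) of each gene list that passed camera's test in any comparison, with bars for the SD of the members. Filled points passed with the preset correlation and red points also with an estimated correlation. Interferon response and cumulus and granulosa markers are red in both comparisons against control and not between the low glucose media.

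BHB in the low glucose medium left blastocysts with a similar set of lower transcripts against control. MX1 fell from 98.2 ± 18.0 CPM in control to 14.3 ± 6.42 CPM with BHB, LUM from 139 ± 59.2 to 12.3 ± 0.154 CPM, and VCAN, the gene of the proteoglycan versican, from 74.9 ± 1.52 to 7.71 ± 2.29 CPM (SD, n = 3 each). PDLIM3, which encodes a protein of actin filaments, fell from 10.8 ± 0.753 to 0.488 ± 0.0393 CPM, and ADAM12, a metalloprotease gene, from 3.01 ± 0.359 to 0.270 ± 0.0349 CPM. In edgeR's quasi-likelihood test, 227 genes were lower and 1 was higher at an adjusted p under 0.05. The median of the falls was -1.95, or 3.88-fold, and 183 of them belong to none of the fixed gene lists. The gene that rose, ENSBTAG00000049212, has no symbol in the table and was chosen after its values were seen. It had 246 counts over the BHB libraries and 0 over the control libraries, at least 85.7-fold higher against a floor of 3 counts over the group, and lost its call without control replicate 3, BHB replicate 2 or BHB replicate 3 (fitted log2 values 9.35, 9.04 and 9.45, which depend on the prior count).

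Interferon response genes fell with BHB too, 18 of 34, or 26 adjusted over the list alone, with a median log2 fold change of -2.00 (camera adjusted p = 1.99e-51, and 0.0295 as an adjusted p with an estimated correlation). MX1 changed by -2.78 (SE 0.322, edgeR adjusted p = 0.00325), IFIT5 by -2.58 (SE 0.377), USP18 by -1.78 (SE 0.238) and DDX58 by -1.91 (SE 0.243). Cumulus and granulosa cell markers fell in the same libraries by 0.94 in median, with 5 of 23 genes lower, or 8 adjusted over the list alone (camera adjusted p = 0.0336 with an estimated correlation), and by 0.62 without control replicate 1. LUM changed by -3.50 (SE 0.447), DCN by -2.56 (SE 0.367) and VCAN by -3.28 (SE 0.482, edgeR adjusted p = 0.00578). Matrix and adhesion genes had 8 falls among 38, or 13 adjusted over the list alone, and a median of -0.46 (camera adjusted p = 0.0742 with an estimated correlation), or -0.19 without control replicate 1 and -0.71 without BHB replicate 1. COL5A1 changed by -2.49 (SE 0.369), CD44 by -2.37 (SE 0.329), VIM by -1.77 (SE 0.242) and ITGAV by -1.46 (SE 0.223).

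The other lists that passed with the preset correlation all lost their call with an estimated correlation. Hypoblast markers had a median of -0.12 and 4 falls among 27, also 4 adjusted over the list alone (camera adjusted p = 0.186 with an estimated correlation), with SERPINH1 at -1.36 (SE 0.157) and BMP2 at -1.84 (SE 0.243). Their median turned to 0.03 without control replicate 1 and was -0.03 without control replicate 3, -0.07 without BHB replicate 1, -0.01 without BHB replicate 3 and -0.08 without low glucose replicate 1 or 2. GATA4 changed by -1.13 (SE 0.244), a call lost without any single control replicate (-1.22, -1.15 and -0.98), low glucose replicate 3 (-1.13) or BHB replicate 1 (-0.94) or 3 (-1.05). Imprinted genes had a median of -0.23 and 3 falls among 24, or 4 adjusted over the list alone, and PEG10 changed by -1.53 (SE 0.219). Signalling genes of the WNT, TGF-beta, FGF and Hippo pathways had a median of -0.18 and 1 fall, ID3 at -2.29 (SE 0.357), or 4 adjusted over the list alone. Hypoxia response genes had a median of -0.17 and 1 fall, HIF1A at -0.99 (SE 0.180), also 1 adjusted over the list alone. For these last 3 lists the camera adjusted p was 0.0742 with an estimated correlation. Mitochondrially encoded transcripts had a median of -0.35 (camera adjusted p = 0.848 with an estimated correlation), amino acid and integrated stress response genes 0.29 (adjusted p = 0.527 with an estimated correlation) and trophectoderm markers 0.20 (adjusted p = 0.349 with an estimated correlation), with no member past the threshold. Without BHB replicate 2, the library poorest in mitochondrial transcripts, their call was lost (-0.06), as was that of the trophectoderm list without control replicate 1 (0.10) and of the signalling list without control replicate 3 (-0.14). Other medians moved with calls kept: mitochondrial transcripts to -0.22 without BHB replicate 1 and -0.85 without BHB replicate 3, trophectoderm markers to 0.31 without control replicate 3 and 0.13 without BHB replicate 2, stress response genes to 0.17 without control replicate 1, imprinted genes to -0.14 without BHB replicate 1 and signalling genes to -0.12 without BHB replicate 2. HIF1A lost its call without control replicate 2 (-0.88), control replicate 3 (-0.96) or BHB replicate 3 (-1.05).

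IGFBP7 changed by -1.81 (SE 0.190, edgeR adjusted p = 0.00240) and GSTA1 by -2.89 (SE 0.397). Genes of ketone use did not pass with BHB: BDH1 stood at 0.02 (SE 0.278), OXCT1 at -0.09 (SE 0.198) and SLC16A1 at 0.12 (SE 0.169). Adjusted over each list alone, 1 ketone body gene and 1 glycolysis gene were lower. POU5F1, NANOG, CDX2, GATA3, GATA6 and SOX17 did not pass either, with log2 fold changes of 0.15 (SE 0.106), 0.03 (SE 0.355), 0.22 (SE 0.210), 0.14 (SE 0.139), 0.29 (SE 0.148) and 0.74 (SE 0.474). The count of 228 genes fell to 91 without control replicate 3, 94 without BHB replicate 3, 122 without control replicate 1 and 133 without BHB replicate 1. DESeq2 gave 441 genes.

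The falls in both media were largely of shared genes. Of the genes that fell, 206 passed in both comparisons, MX1, LUM, COL5A1 and PEG10 among them, 127 in low glucose alone and 21 with BHB alone. Of the latter sets, 126 and 20 also lay below 0 in the other medium, though the shared controls favour the same sign. Of all 354 genes, 0 passed between the low glucose media, but 274 lay higher with BHB than without, and the median difference was 0.29. Against control, their median log2 fold change was -2.12 in low glucose and -1.72 with BHB. Most of the 354 were called in low glucose, and such a choice favours deeper falls there. Whether the falls were shallower with BHB was not tested. Simulated groups with no difference, set against shared controls, gave 0 shared genes in 20 simulations, and independent lists of these sizes would share 4.59. The simulated media call almost no genes and the independent lists leave out the shared controls, so neither is a chance value for the 206. The log2 fold changes of all tested genes correlated across genes at r = 0.72, against 0.50 (SD 0.0131) in the simulations, and their covariance was 0.368 against 0.139, a difference of 0.229. Genes are not independent replicates, and as 3 control libraries cannot be split into parts of at least 2 libraries, part of the excess may come from the shared controls, or from replicate numbers that pair the libraries of both low glucose media.

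**Figure D4:**
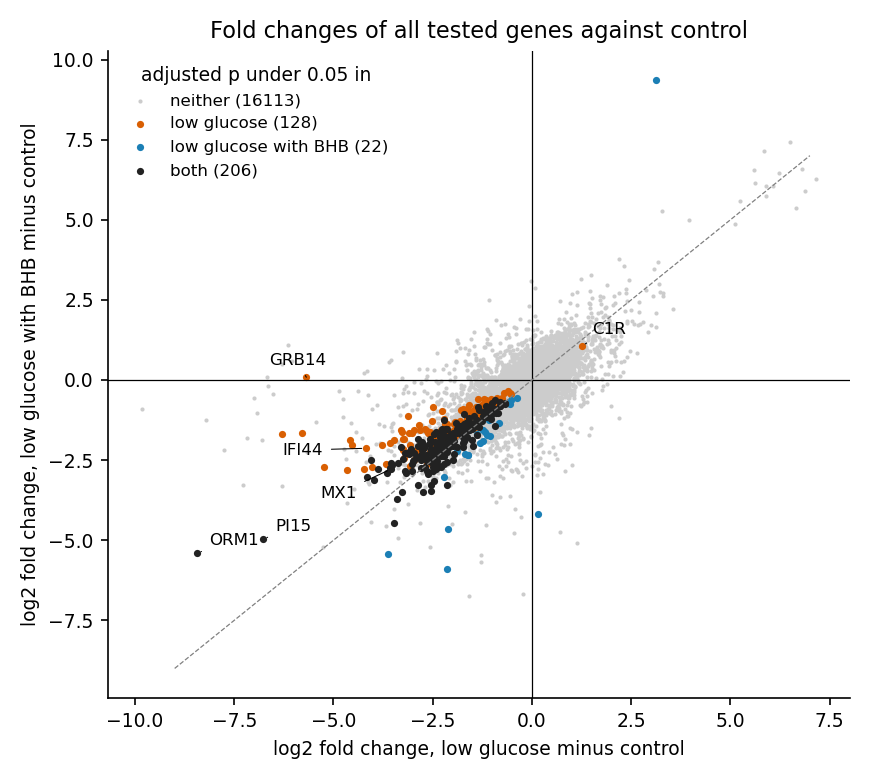
Log2 fold change against control in low glucose (x axis) and low glucose with BHB (y axis) for the 16469 tested genes, coloured by where the adjusted p was under 0.05, with a dashed line of equal change. ORM1, PI15 and GRB14 had 1 to 3 counts in low glucose, so their positions depend on the fit. Of the coloured points, 206 passed in both comparisons.

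Between the low glucose media with and without BHB, no gene passed the test, and the interferon and matrix genes lay low in both. MX1 was measured at 14.3 ± 6.42 CPM with BHB and 8.39 ± 2.48 CPM without, and LUM at 12.3 ± 0.154 and 14.3 ± 9.21 CPM (SD, n = 3 each). BDH1 and OXCT1, enzymes of ketone use, differed by 0.06 (SE 0.278, 95% interval -0.55 to 0.66) and 0.31 (SE 0.198, -0.12 to 0.74). HDAC1 differed by -0.07 (SE 0.130, -0.35 to 0.22). In edgeR's quasi-likelihood test 0 genes had an adjusted p under 0.05 and 270 had an unadjusted p under 0.05, fewer than the 823 of chance. limma-voom gave 0 genes and DESeq2 gave 2.

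The 2 genes of DESeq2, both without a symbol and chosen after their values were seen, were ENSBTAG00000047356, lower with BHB at -4.36 (DESeq2 adjusted p = 0.000643), and ENSBTAG00000049212, higher at 6.40 (DESeq2 adjusted p = 0.00199). The latter had 246 counts over the BHB libraries and 3 over those of low glucose, a ratio of 84.3 (exact 95% counting interval 28.5 to 412). Among genes with the smallest p that did not pass in edgeR, GRB14, an adaptor gene of the insulin receptor, had 74 counts with BHB and 1 without, a ratio of 76.1 (13.2 to 3047). The control libraries held 74 counts of GRB14 as well, so it was low in low glucose alone and not raised by BHB above control. Its call as lower in low glucose than in control was lost in 9 of 9 leave-out fits. IQUB had 54 counts with BHB and 0 without, at least 18.5-fold higher against a floor of 3 counts over the group, or 12.1-fold without BHB replicate 1. RPL12, a ribosomal protein gene, was measured at 124 ± 50.8 CPM with BHB and 227 ± 24.6 CPM without.

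Gene lists differed between these media with the preset correlation alone, and no member passed, 0 also adjusted over the list alone. Mitochondrially encoded transcripts were lower with BHB by a median of -0.72, with CYTB at 2241 ± 983 CPM against 3969 ± 1659 CPM. Ribosomal protein genes were lower at -0.14, nuclear genes of oxidative phosphorylation at -0.09 and cholesterol genes at -0.18. Interferon response genes were higher at 0.53, with 4 of 34 members below 0, and amino acid and integrated stress response genes at 0.15. With an estimated correlation the camera adjusted p was 0.528 for the mitochondrial and the interferon list and 0.984 for the other 4. The cholesterol list lost its call without low glucose replicate 1 (-0.07) or replicate 2 (-0.06) and turned to 0.07 without BHB replicate 1. The amino acid list lost its call without BHB replicate 2 (0.07) or replicate 3 (0.12), and without low glucose replicate 1 (0.02) its test turned. The mitochondrial median was -0.37 without low glucose replicate 1, -0.42 without BHB replicate 2 and -1.17 without BHB replicate 3, and the interferon median 0.26 without BHB replicate 2. The ribosomal median was -0.09 without low glucose replicate 2 or BHB replicate 3 and -0.23 without low glucose replicate 3 or BHB replicate 2, that of oxidative phosphorylation -0.06 without BHB replicate 1, that of cholesterol genes -0.37 without low glucose replicate 3, -0.38 without BHB replicate 2 and -0.29 without BHB replicate 3, and that of amino acid genes 0.24 without low glucose replicate 3.

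In simulated data for this comparison, 46.3% of genes changed 2-fold and 71.0% of genes changed 4-fold were recovered with 3 libraries per group. The simulated libraries held no pairing by replicate number. In the real ones, edgeR gave 270 genes at an unadjusted p under 0.05 against 823 by chance, so recovery there may be lower.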

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

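Thinning and the comparison of both low glucose media together were tests chosen after the results were seen. Changed genes against control numbered 583 in low glucose and 441 with BHB by DESeq2, which called all 334 and 228 genes of edgeR, and DESeq2 called 2 between the low glucose media. The cause was not tested. Leaving out a library gave 196 to 391 genes in low glucose (196 without control replicate 3, 197 without low glucose replicate 2), 91 to 257 with BHB (91 without control replicate 3, 94 without BHB replicate 3, 122 without control replicate 1, 133 without BHB replicate 1) and 0 between the low glucose media. These fits hold fewer samples. For both low glucose media together the range was 306 to 496 against 499 with all libraries, with 306 without control replicate 3 and 323 without control replicate 1. RLE factors gave 330, 227 and 0 genes, no filter 373, 261 and 0, a mean count of at least 50 gave 347, 237 and 0, the 6 libraries compared 388, 226 and 0, limma-voom 346, 263 and 0, and thinning 331 to 342, 222 to 231 and 0. Falls made up at least 97.7% of calls against control in each of these fits. With the replicate block there were 405, 278 and 0 genes. Against control the replicate numbers do not pair the samples by the rule used (correlations 0.0417 to 0.144), although 8 of 9 libraries correlated best with their own number, a hint from the data and not from the design. Between the low glucose media the block changed no call, with a smallest adjusted p of 0.606 in edgeR, against 0.870 to 1.00 over the leave-out fits. The overlap of genes changed against control in both low glucose media, all of them lower, numbered 206, and 205 with RLE factors, 212 with a mean count of at least 50 and 252 with the block.

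Lists past camera's test numbered 2, 2 and 0 with an estimated correlation, against 11, 10 and 6, and 7, 7 and 0 with fry, which tests whether the genes of a list move and not whether they move more than others. Leave-out fits gave 9 to 13, 9 to 13 and 5 to 7. Between the low glucose media, the direction of camera's test turned for the amino acid and integrated stress response list without low glucose replicate 1, while its median stayed above 0 (0.0220, over leave-out fits 0.0220 to 0.235). Direction and median both turned for the cholesterol list without BHB replicate 1 (0.0658, over leave-out fits -0.377 to 0.0658). The cause was not tested. No passing named gene reversed. In leave-out fits, 16 of 53 passing named genes in low glucose and 23 of 46 with BHB lost their call at least once. The ratio of distances between and within groups was 1.10 (SD 0.0497 over libraries) for the 500 most variable genes and 1.05 over all tested genes. Depth limits genes such as ORM1 and GRB14, with 1 count over the low glucose libraries.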

Other observations

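Tests of the added cell type lists, of cumulus or stromal cells, hypoblast share, interferon tau and a shared source, thinning, and the comparison of both low glucose media together with its splits were chosen after the results were seen, although the bounds for thinning and for all splits were set before those were run. A list of fibroblast and stromal markers, which shares 3 genes with the fixed matrix list and 3 with the fixed cumulus list, had 8 of 21 genes lower in low glucose and 7 with BHB, with medians of -1.72 and -1.47 (camera adjusted p = 0.00981 and 0.0117 with an estimated correlation). CDH11, a cadherin gene of mesenchymal cells, stood at 24.1 ± 9.97 CPM in control, 4.04 ± 1.10 in low glucose and 4.99 ± 1.13 with BHB, and PDGFRB, a growth factor receptor gene, at 14.3 ± 2.62, 3.06 ± 0.984 and 3.00 ± 1.25 CPM (SD, n = 3 each). Both genes were chosen after their values were seen. A list of steroidogenic and granulosa identity genes had 4 and 3 of 16 genes lower, with medians of -0.96 and -0.90 (camera adjusted p = 0.00981 and 0.0185 with an estimated correlation). It shares 5 genes with the fixed cumulus list, 1 with the hypoblast list and 1 with the trophectoderm list, so these lists are not separate evidence. Its member NR5A1, a nuclear receptor gene of steroidogenic cells chosen after its values were seen, stood at 7.54 ± 1.10, 1.10 ± 0.207 and 1.95 ± 0.877 CPM. Lists of smooth muscle and theca markers (medians -0.41 and -0.12, adjusted p = 0.354 and 0.215 with an estimated correlation) and of endothelial markers (0.02 and 0.11, adjusted p = 0.941 and 0.893 with an estimated correlation) did not pass. None of these 4 lists passed between the low glucose media. The p-values of these lists were adjusted over the 4 alone, not together with the fixed lists. Lists chosen after the results were seen give no independent evidence on these cells. NR5A1 with BHB lost its call without control replicate 3 (-1.81) or BHB replicate 3 (-1.90).

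With both low glucose media set together against control, 496 genes were lower and 3 higher in edgeR at an adjusted p under 0.05. Those higher were C1R, a complement protease gene (1.16, SE 0.249), NFATC1, a transcription factor gene (0.72, SE 0.177), and DUSP8, a phosphatase gene (0.45, SE 0.105), chosen after their values were seen. Without control replicate 1 these 3 calls were lost and all 323 genes that passed were lower, and without control replicate 3 the count was 306.

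The genes lower in both low glucose media included markers of cells outside the embryo, and a candidate explanation is a share of cumulus, granulosa or stromal cells in the control pools. The fixed cumulus and granulosa list fell in both comparisons with an estimated correlation (larger adjusted p = 0.0336), while epiblast and trophectoderm medians lay between 0.12 and 0.20. Of its 23 genes, 16 reached 1 CPM in the low glucose media too and 1 is also in the matrix list, and embryos were washed but no removal of cumulus cells is described in the labels. Its most abundant genes in control all had lower values in both media: SERPINE2, at 244 CPM, fell with calls lost in 7 and 6 of 9 leave-out fits (-0.56 and -0.62 without control replicate 1), COL1A2, at 211 CPM, stood at -1.34 and -1.29 without passing, and LUM, at 139 CPM, fell. Of less abundant members, HSD3B1 (45.3 CPM), CYP19A1 (21.2 CPM) and FSHR (4.18 CPM) did not pass, with HSD3B1 at 0.39 in both. DCN and NR5A2, at 7.11 to 13.8 and 10.3 to 13.3 CPM over the control libraries, fell in both. NR5A2 with BHB lost its call in 4 of 9 leave-out fits. SERPINE2, COL1A2, HSD3B1, CYP19A1 and FSHR were chosen after their values were seen. The hypoblast median lay at least 1.83 above that of the falls, past the bound set against a lower share of hypoblast cells. The falls were picked for being lower, so a gap is built in, and a lower hypoblast share stays open. Thinning, which left at least 97.4% as many falls, argues against lower depth. Lower expression of these genes within the embryo, through the medium, also stays open and untested.

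Lower interferon tau, the trophoblast signal that induces such genes in cattle, might account for the interferon response genes. Of 8 listed interferon tau genes, only 3 were measured. Near-identical copies share reads, so these 3 members were summed, at 12.1 ± 4.16 CPM in control (SD, n = 3). The change of the sum was 0.02 (SE 0.443) in low glucose and 0.21 (SE 0.443) with BHB, with a lower 95% bound of -0.94 at the lowest. For the transcripts of these 3 members, that narrowly argues against a fall of 1 log2 unit but not against a smaller fall. Listed copies that were not measured, and the protein, are not covered. Alone, IFNT3 had bounds of -0.89 and -0.68, while IFNT2 (-1.37 and -1.26) and IFN-TAU, at 0.130 CPM in control (-3.97 and -6.76), were too uncertain to exclude one. If interferon and matrix transcripts came from the same cells, their levels could move together across the 6 low glucose libraries, but Pearson's r was -0.29 (exact permutation p = 0.585) and Spearman's rho -0.429 (exact permutation p = 0.419, n = 6), with r at -0.098 without the 2 farthest libraries, the only relation computed. That value met the bound first set against a shared source, at or below 0. As its 95% interval, from -0.892 to 0.682, holds values the explanation allows, a condition added after r was seen, a shared source stays open. Interferon response genes were also low in these 6 libraries, at a mean log2 CPM of 1.34 to 2.77, against 3.87 to 4.09 in control. What remained there need not come from a source in the control pools, so r cannot decide the question.

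For the contrast of both low glucose media with control, 1 of 84 splits into 3 and 6 libraries gave as many as 499 genes. That was the real one, which met the bound set against chance. The highest other split, with 26 genes, set replicate 1 of each medium apart. The contrast was chosen after the results were seen, and the splits ignore any pairing by replicate number, so chance is not excluded. For each single medium against control there are 10 splits, too few for a share under 0.05. In low glucose the real split gave 334 genes and the highest other 0, and with BHB 228 and 0, with 1 of 10 splits as large. Between the low glucose media the real split gave 0 genes, so all 10 of 10 splits gave as many, and the highest other gave 69. That split set low glucose replicates 1 and 2 with BHB replicate 2 against the rest, and the next highest gave 2. It was picked as the highest of 10, and what sets these samples apart was not tested. Among the 4 splits that part all pairs of replicate numbers, the real one included, the highest count was 0.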
